A study of Salmonella enterica subsp. enterica serovar Typhimurium with 6 samples.

How the data were processed

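Total RNA from 6 samples of Salmonella Typhimurium UMR1 was sequenced, 3 controls and 3 with 15 µM clarithromycin, all with 1.5% DMSO. Per the labels' protocols, overnight cultures grown at 37 °C were diluted to an OD600 of 0.02 in LB lacking salt. They were then shaken at 150 rpm and 28 °C for 16 h in flasks filled to 60%, which limits oxygen. Ribosomal RNA was depleted with RiboMinus before paired reads of 75 bases were made on a NextSeq instrument. Ribosomal RNA left after depletion takes reads from other transcripts and can differ between libraries.

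The authors deposited one table of raw counts per annotated feature, 1 column per library, with no normalisation. Per the submitters' processing notes, bcl2fastq 2.20.0.422, STAR 2.5.2b and featureCounts 1.5.1 were used. Per the file headers, featureCounts was run on an annotation of the ATCC14028 genome with strand setting 2, which counts reads on the reverse strand of a feature. Whether the library kit marks strand in that orientation is not given in the sources used here, so the setting was not checked, and statements on strand rest on it. No option for read pairs, multi-mapping reads or overlapping features is set there, and the names of the alignment files give read 1. By that tool's defaults, reads that map to several places or to overlapping features were then not counted, so repeated genes, such as those for ribosomal RNA, are undercounted and uncertain, and so are bases shared by overlapping features. The same table gives each feature's position and its length, a value of another kind. The features lie on 1 sequence, the chromosome, and plasmid genes were not analysed here. The trimming and alignment settings are not given in the sources used here.

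The table holds 4989 features, of which 29 had no count. It gives locus tags without gene names. None of the tags (0 of 4989) matched the 4717 genes in the table of names at hand, which belongs to strain LT2 (assembly ASM694v2). Names were not guessed from order or coordinates. Therefore the 43 gene lists fixed before the data were examined, including the list of rdar matrix genes, were not tested, and the rule that would have named list members gave no result. Of the other rule, fixed at the same time, the 12 largest rises and 12 largest falls were taken among features with an adjusted p below 0.05, no overlap between groups and a mean of at least 20 CPM. Only the first 2 of each are named by tag, and the rest are described by the stretches they lie in. Stretches, same-strand runs and size classes were defined after the data were examined. There were 125 features with 2 entries in the annotation, identical in position for 122. Those of 74 to 95 bases are called transfer RNA size (85 features). Those of 116, 1554 to 1556 or 3011 to 3113 bases are called ribosomal RNA size (22 features). The LT2 table lists 85 transfer RNA genes of 71 to 91 bases and 22 ribosomal RNA genes of 120 to 3093 bases. Some members of each class lie outside these lengths. The class limits were set after the data were examined, so the equal totals are no independent check. The size classes are therefore stand-ins, since the deposited table does not mark RNA type. The planned share of ribosomal RNA was computed on the stand-in.

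Counts were analysed in R 4.3.3 with edgeR 4.0.16. Features were filtered with filterByExpr, which left 4115, libraries were scaled with TMM factors (0.704 to 0.831 in controls and 1.27 to 1.41 with clarithromycin), and a quasi-likelihood F test (glmQLFit, glmQLFTest) compared the groups with Benjamini-Hochberg adjustment. The biological coefficient of variation was 0.167. CPM values are TMM-normalised, and shares of reads are not. Standard errors of log2 fold changes were derived from the fitted coefficient and its F statistic. Sets were tested with camera (preset correlation 0.01) and fry of limma 3.58.1. Shares and totals, 7 measures, were compared with exact two-sided permutation tests over 20 assignments in scipy 1.17.1. Figures were drawn with matplotlib 3.10.9. Replicates of one group differed beyond sampling noise, with a chi-square per degree of freedom of 14.1 to 34.2, so none was counted as a duplicate. Replicate numbers follow sample order and pair nothing. No tested feature was without counts in all libraries of a group. Libraries held 2252839 to 4951945 counted reads, and features with few reads carry a larger counting error. CPM stands for reads scaled to equal effective library size.

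The method was tested on simulated counts for the 4115 features of this comparison. It called 78 of 100 features changed 2-fold, 96 of 100 changed 4-fold and 5 of 3915 unchanged features. Camera called 0 of 40 unchanged sets and 2 of 2 changed sets. Simulated features were drawn independently and sets were picked without regard to position, so members were not correlated as chromosomal neighbours can be. Most simulated features were unchanged, unlike in the data. The simulation therefore does not vouch for camera on same-strand runs, where wrong splits of the libraries passed 8 to 22 runs.

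Alternatives fixed before the data were examined were upper quartile and relative log expression (RLE) factors, library size alone, DESeq2 1.42.0, limma-voom, a robust fit, no filter, a filter of at least 10 CPM in 3 libraries, removal of structural RNA features or of the 10 most abundant features, a test against 1.5-fold (glmTreat), and each library left out in turn. Structural RNA features were removed by a stand-in, all features with 2 entries in the annotation, which also drops features of other sizes. Added afterwards were thinning to the smallest library, a correction for feature length alone, other gaps between run members, set tests with other settings, and library size alone without abundant or doubly entered features. A planned correction for length and GC content together was not run, because no genome sequence was used here; the correction for length alone took its place.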

Results

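RNA was sequenced from cell aggregates of Salmonella enterica serovar Typhimurium UMR1, a Nalr derivative of strain ATCC14028 that forms rdar biofilm. Rdar (red, dry and rough) describes the colony look given by an extracellular matrix of curli fimbriae and cellulose. Of the 6 libraries, 3 were controls and 3 came from bacteria exposed to 15 µM clarithromycin, a macrolide antibiotic that binds the large ribosomal subunit. All samples held 1.5% DMSO. The study's title states its purpose as an antibiofilm effect of clarithromycin, and the single comparison asked which transcripts differed between treated and control aggregates. The libraries held 2252839 to 4951945 counted reads over 4989 annotated features, with 2958125, 2432599 and 2252839 reads in control replicates 1, 2 and 3 and 2866119, 3280591 and 4951945 in clarithromycin replicates 1, 2 and 3. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Features are given by their position on the ATCC14028 chromosome, because the deposited table pairs its locus tags with no gene names. For this reason no statement on curli, cellulose or any other named gene group was made.

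Clarithromycin was accompanied by a change in 2267 of 4115 tested features (55.1%), of which 1100 were higher and 1167 lower than in controls (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). At least a 2-fold change was fitted for 1315 features, 679 higher and 636 lower. At least 4-fold changes were fitted for 183 higher and 153 lower features. The normalised read counts of the 3 control and the 3 treated libraries did not overlap for 2571 features (62.5%), where chance gives 10%. Correlations of log2 normalised counts across features were 0.967 to 0.989 between libraries of one group and 0.837 to 0.855 between groups. The numbers higher and lower depended on the scaling, and so did which features were called. Library size alone called 2785 features and kept 1474 of the 2267 calls in the same direction. With trimmed-mean (TMM) factors 48.5% of the called features were higher, and with library size alone 86.6% were higher, 2411 against 374. The median log2 fold change of the tested features was -0.06 with TMM factors and 0.75 with library size alone, so each change below is relative to the bulk of the features.

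**Figure D1:**
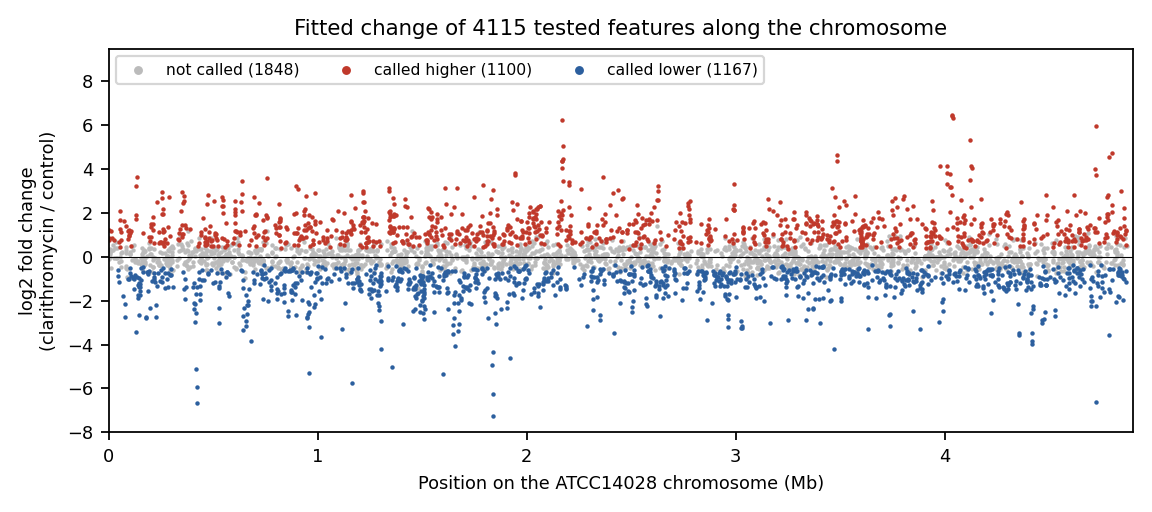
Fitted log2 fold change (clarithromycin over control, vertical axis) of each of the 4115 tested features against its midpoint on the ATCC14028 chromosome in megabases (horizontal axis). Red points were called higher (1100), blue points lower (1167) and grey points were not called at an adjusted p of 0.05, and both kinds of call occur along the whole chromosome; with library size alone the counts were 2411 and 374.

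The steepest rise was at 4026013 to 4038229 on the minus strand, where 6 consecutive tested features were all called higher. Their summed level was 27.2 ± 5.29 normalised reads (CPM, scaled to equal library size) in controls and 1112 ± 199 with clarithromycin (mean ± SD, n = 3), a 40.9-fold difference, with member log2 fold changes of 2.83 to 6.47 (median 5.05). Within it, STM14_RS20175 (4033878 to 4034510) rose from 1.53 ± 0.297 to 141 ± 27.8 CPM, a log2 fold change of 6.47 with a standard error of 0.29 (edgeR adjusted p = 5.19e-08). Its neighbour STM14_RS20180 (4034503 to 4037055), which overlaps it by a few bases, rose from 6.67 ± 3.45 to 597 ± 136 CPM, a log2 fold change of 6.44 with a standard error of 0.32 (edgeR adjusted p = 8.31e-08). The steepest single fall was that of STM14_RS09550 (1837096 to 1837602, plus strand), from 1359 ± 990 to 9.0 ± 1.69 CPM, a log2 fold change of -7.24 with a standard error of 0.67 (edgeR adjusted p = 4.73e-06). Its control libraries were far apart, at 305 CPM in replicate 1 against 2269 and 1503 CPM in the others, but each exceeded every treated library. Without control replicate 2 its log2 fold change was -6.60. STM14_RS02465 (420889 to 422340, plus strand) fell from 1072 ± 99.1 to 10.6 ± 3.11 CPM, a log2 fold change of -6.65 with a standard error of 0.25 (edgeR adjusted p = 2.22e-08).

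The 12 features with the largest rise and the 12 with the largest fall among 727 and 881 that met the naming rule lay in 16 stretches, 8 higher and 8 lower. A stretch is an unbroken series of tested features called in one direction, so all its members passed the test by construction, and stretches were defined after the data were examined. Members of a stretch changed by unequal amounts, so a summed level can follow 1 abundant member. After the region at 4026013, the largest change in summed level among the higher stretches of more than 1 feature was at 3484114 to 3486985 (minus strand, 4 features), from 492 ± 76.7 to 6728 ± 524 CPM, 13.7-fold, with member log2 fold changes of 1.36 to 4.65 (median 3.00). At 4131068 to 4132916 the sum of 2 features rose from 35.1 ± 5.09 to 347 ± 62.0 CPM, with log2 fold changes of 0.76 and 4.07. At 4717965 to 4723378 (minus strand) 5 features rose from 11.8 ± 0.354 to 108 ± 29.5 CPM, with log2 fold changes of 1.13 to 5.97 (median 3.72). The 4 features at 4008528 to 4011502 rose from 155 ± 17.3 to 1375 ± 35.1 CPM, and the 5 at 4122664 to 4129075 (plus strand) from 256 ± 51.1 to 1980 ± 186 CPM. Their median log2 fold changes were 3.57 (1.27 to 4.15) and 2.29 (0.81 to 5.34). A feature that stood alone, at 4784875 to 4786116, rose from 7.43 ± 2.41 to 178 ± 6.26 CPM.

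Among the falls, the pair of features at 1164548 to 1165490 (plus strand) went from a sum of 5490 ± 948 to 127 ± 7.35 CPM. One member carried this fall, with a log2 fold change of -5.77, and the other had -1.18. The 4 features at 1836247 to 1838500 (plus strand), which include STM14_RS09550, went from 6781 ± 4496 to 195 ± 16.5 CPM, with the control replicate 1 at 1851 CPM and the others at 10655 and 7837 CPM, and member log2 fold changes of -7.24 to -4.32. The 5 features at 418670 to 425345, which include STM14_RS02465, went from 3786 ± 394 to 162 ± 18.8 CPM, with log2 fold changes of -6.65 to -1.39 (median -5.10). The pair at 1920255 to 1920757 (minus strand) went from 2330 ± 867 to 142 ± 1.95 CPM, with log2 fold changes of -4.61 and -0.87. At 1599665 to 1603700 a sum of 2520 ± 1510 CPM went to 308 ± 29.7 CPM, again with control replicate 1 lowest at 837 CPM. One member carried that fall, with a log2 fold change of -5.35, while the median of the 4 was -0.95 and only -0.15 with library size alone. Falls at 4724580 to 4726990, from 320 ± 66.2 to 53.8 ± 1.61 CPM, and at 958765 to 962823, from 823 ± 97.9 to 273 ± 22.5 CPM, had median log2 fold changes of -2.24 (-6.59 to -1.17) and -2.31 (-5.28 to -0.73). With library size alone, the median changes of these stretches kept their sign.

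**Figure D2:**
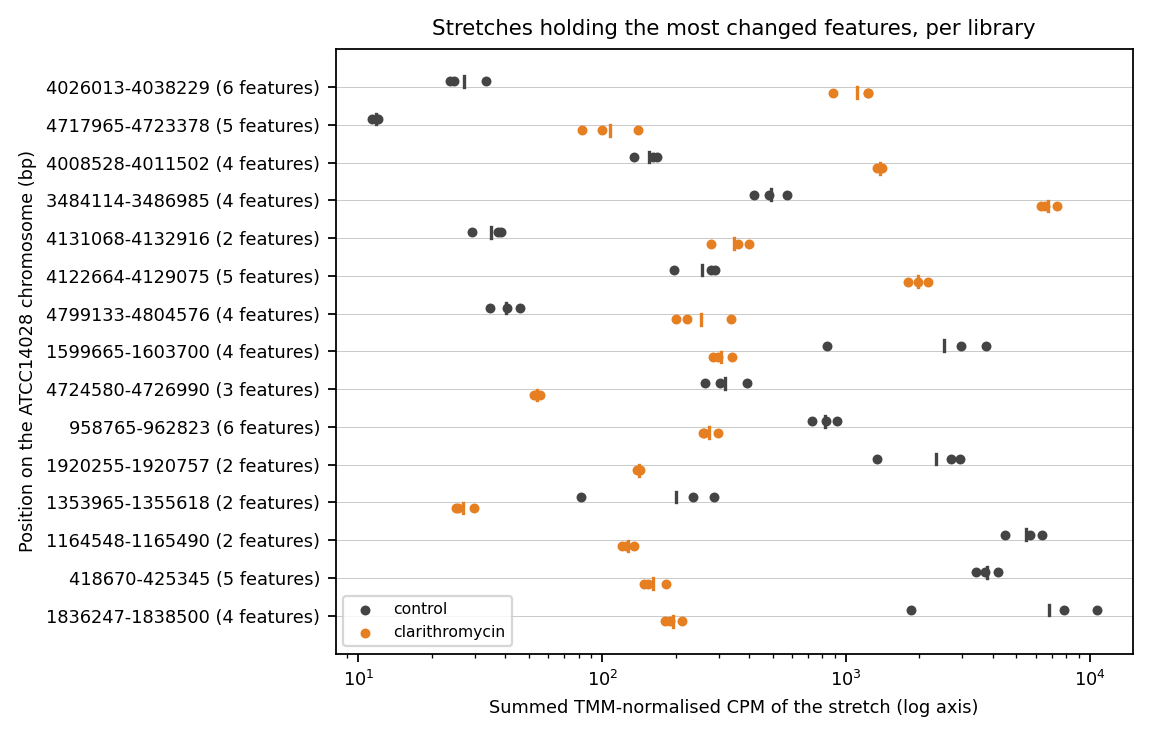
Summed TMM-normalised CPM (horizontal log axis) of the 15 stretches of more than 1 feature that hold the most changed features, by position on the ATCC14028 chromosome (vertical axis). Each point is 1 library, grey for control and orange for clarithromycin, and the short bars are group means. In each stretch the 3 treated libraries lie on one side of the 3 control libraries. This largely follows from the choice of stretches, which hold features picked for no overlap between groups.

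Calls in one direction also formed longer stretches. The longest stretch ran from 3596735 to 3605877 on the minus strand and held 19 consecutive features, all higher, with a median log2 fold change of 0.77 and a summed level that rose from 9161 ± 1205 to 16350 ± 2249 CPM (n = 3). Stretches of at least 8 features numbered 11, 5 higher and 6 lower. When the calls were shuffled over the tested features 1000 times, the longest stretch had a median of 7 and at most 12 features, and no shuffle gave more than 3 stretches of at least 8 features. The shuffles scattered calls over single features, so clustering beyond close same-strand neighbours was not tested. The longest stretch itself holds the same-strand runs (defined below) at 3596735 to 3599590 and 3599737 to 3605268. The largest median rise among the long stretches was 4.35 at 2167078 to 2175989, where 9 features had a summed level of 11.6 ± 0.263 CPM in controls and 128 ± 20.0 CPM with clarithromycin. The 12 features at 1215594 to 1226260 rose from 71.1 ± 33.8 to 260 ± 54.7 CPM. Control replicate 1 stood apart there, at 109.7 CPM against 56.9 and 46.7, and without it the median log2 fold change went from 1.83 to 2.47. The 9 features at 1339441 to 1345958 rose from 413 ± 164 to 1525 ± 236 CPM. In the other direction, the 12 features at 141119 to 155075 (plus strand) fell from 2711 ± 293 to 759 ± 117 CPM, and the 10 at 4410143 to 4425561 from 9184 ± 1450 to 3638 ± 532 CPM. The latter stretch includes a feature of ribosomal RNA size, a class whose fall rests on the scaling. Its sum fell 2.52-fold while the median log2 fold change was -2.32 (-3.97 to -0.84), so the sum may follow abundant members. That median was -2.47 without features of 2 entries and -1.50 with library size alone. The 9 features at 4828712 to 4837764 had a median log2 fold change of -0.73, which turned to 0.08 with library size alone.

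Same-strand runs, defined as features of one strand separated by at most 50 bases, were taken as approximate transcription units. Of 144 runs with at least 4 tested members, 10 had every member called higher and 15 had every member called lower, while 32 held calls in both directions and 8 held none. In the run at 129769 to 134450 (minus strand) 4 features rose from a sum of 34.0 ± 3.12 to 250 ± 12.7 CPM. In the run at 3026606 to 3030037 (plus strand) 4 features fell from 867 ± 341 to 98.6 ± 5.62 CPM, and in that at 1670664 to 1677317 (plus strand) 4 features fell from 706 ± 200 to 102 ± 20.5 CPM. The 5 features at 3712611 to 3721980 (minus strand) fell from 2139 ± 171 to 872 ± 77.8 CPM. These 4 runs kept their direction under the 3 other scalings. As sets, 22 runs passed camera with a preset correlation of 0.01 (10 higher, 12 lower). With an estimated correlation no run passed, the smallest adjusted p in limma's camera being 0.797, and 3 runs had an unadjusted p below 0.05. By fry, which tests whether a run's members moved one way on balance, 80 of the 144 runs passed. Fry does not compare a run with other features, and 55.1% of all tested features were called, so this count does not set runs apart.

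Features of the size of structural RNA genes were examined as classes, chosen after the data were examined. Of 65 tested features of transfer RNA size, 24 were higher and 2 lower over all tested features, and 23 and 2 when adjusted over the list alone. The class median log2 fold change was 0.46 (mean 0.59) and limma's camera gave an adjusted p = 0.00954, which was lost with an estimated correlation (adjusted p = 0.403) and without clarithromycin replicate 3 (median 0.26, unadjusted camera p 0.0551). The unadjusted camera p was 0.00318 in the main fit. It rose to 0.0382 without control replicate 2 and to 0.0334 with library size alone, before any adjustment over the classes. Their share of all reads was 0.219 ± 0.0498% in controls and 0.454 ± 0.221% with clarithromycin, with 0.708% in clarithromycin replicate 3. After TMM scaling the summed level of the class was 2910 ± 871 CPM in controls and 3436 ± 1822 CPM with clarithromycin, a difference within the spread. Of 22 features of ribosomal RNA size, 1 was higher and 8 lower, with a median log2 fold change of -0.47 that turned to 0.35 with library size alone, and the class did not pass camera (limma adjusted p = 0.114). Ribosomal RNA had been depleted before sequencing. Features of this size still took 23.3% ± 2.18 of counted reads in controls and 20.9% ± 1.22 with clarithromycin (SD, n = 3). The groups overlapped (exact permutation test, two-sided, p = 0.2, Benjamini-Hochberg adjusted over 7 measures 0.2). Reads mapping to several places were by default not counted, so these shares may understate ribosomal RNA. After TMM scaling the summed level of the class was 311648 ± 54364 CPM in controls and 158144 ± 16056 CPM with clarithromycin, a fall that rests on the scaling. Groups of 3 against 3 cannot give an exact p below 0.1. The remaining features with 2 entries in the annotation, of other sizes, were tested as a further class. Of its 12 tested features 0 were higher and 5 lower, with a median log2 fold change of -0.53 that turned to 0.28 with library size alone. It did not pass camera (limma adjusted p = 0.111) but passed fry (adjusted p = 0.00655), which the classes of transfer and ribosomal RNA size did not (adjusted p = 0.0661 for each).

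In controls a few features held most of the reads. The 10 most abundant features took 59.1% ± 3.27 of control reads and 40.6% ± 1.05 of treated reads (SD, n = 3), without overlap (exact permutation test, two-sided, p = 0.1, the smallest possible; adjusted over 7 measures 0.14). The share of 7 of them was lower with clarithromycin and these were called lower, and the share of 3 was higher and these were not called. The calls rest on TMM-normalised counts and do not follow from the shares alone. At 2850578 to 2853690 the share was 4.40% ± 0.561 in controls and 3.91% ± 1.06 with clarithromycin. Its log2 fold change was still -0.99 (edgeR adjusted p = 0.0101). The 3 with higher shares had log2 fold changes of -0.67, 0.02 and -0.31. One of the 7, at 3136621 to 3136833, went from 13.97% ± 1.53 to 6.07% ± 0.330 of reads, a log2 fold change of -2.02 (edgeR adjusted p = 5.80e-05). Another, at 4223708 to 4223932, went from 5.63% ± 1.32 to 1.66% ± 0.0125 of reads, a log2 fold change of -2.57 (edgeR adjusted p = 6.25e-06). A feature at 2897865 to 2898227 fell from 10.5% ± 0.335 to 8.09% ± 0.125, with a log2 fold change of -1.20 (edgeR adjusted p = 0.00129). The features given by position here were picked among the 10 after their values were seen, and others of higher abundance were passed over.

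**Figure D3:**
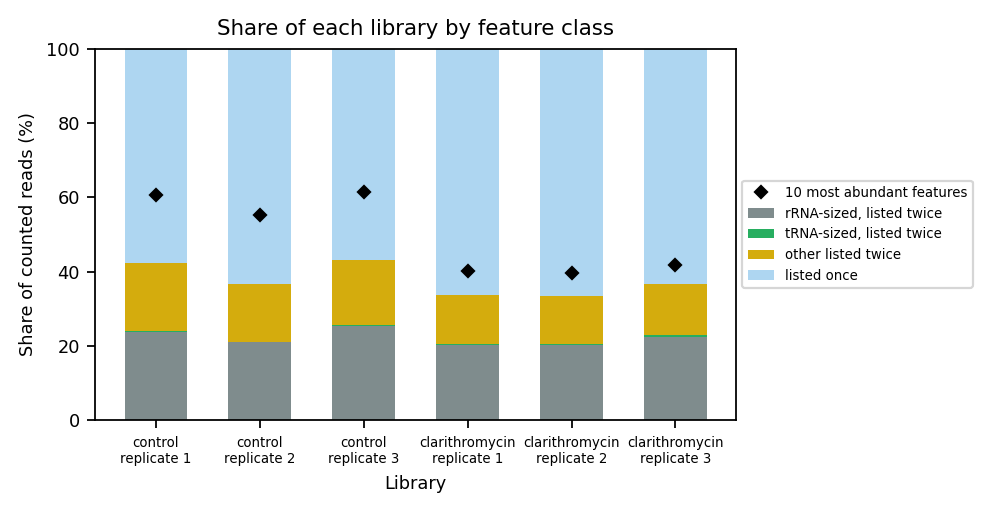
Share of the counted reads of each library (vertical axis, percent) taken by features of ribosomal RNA size, transfer RNA size, other features with 2 entries in the annotation, and features with 1 entry, for the 3 control and 3 clarithromycin libraries (horizontal axis). Black diamonds show the 10 most abundant features, which overlap the coloured classes and took 55.3% to 61.3% of control reads and 39.7% to 41.7% of treated reads.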

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

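The correction for length, the thinning, the run and class tests and the scalings without abundant or doubly entered features were chosen after the data were examined; the other alternatives were planned. The number of changed features (2267) was 1999 to 2177 when single libraries were left out, 2001 with DESeq2 (997 higher, 1004 lower), 2237 with limma-voom, 2269 with RLE and 2250 with upper quartile factors, 2278 without a filter, 2084 with at least 10 CPM, and 2138 after thinning. It was 2259 without features entered in the annotation more than once and 2242 without the 10 most abundant features. It was 1342 with glmTreat against 1.5-fold, which asks for more than a nonzero change. Leaving out single libraries gave 1280 to 1361 features changed at least 2-fold, 975 to 1089 higher, 1014 to 1113 lower, 23 to 29 runs passing camera, and a difference in the share of ribosomal RNA size of -3.55 to -1.40 points. Both the set of called features and the split by direction followed the scaling. Of the 2267 calls, 2220 were kept in the same direction with RLE, 2154 with upper quartile factors and 1474 with library size alone, which called 2785 features. Library size alone gave 2411 higher and 374 lower, and 2114 and 488 without features entered in the annotation more than once; 1458 and 823 were found without the 10 most abundant features. With library size alone the median of features of ribosomal RNA size turned to 0.349 and that of the stretch at 4828712 to 4837764 to 0.0821, since every log2 fold change rises by about the shift of the overall median, from -0.06 to 0.75. For features of ribosomal RNA size the median was -0.835 to -0.343 with single libraries left out; without control replicate 2 (-0.630) it passed camera with an unadjusted p of 0.0368, and the cause was not tested. For transfer RNA size the range was 0.264 to 0.633, the lowest without clarithromycin replicate 3, where the call was lost. That class kept its median of 0.457 but not its call with an estimated correlation (unadjusted p 0.403) or by fry (0.0661). Of the runs, 22 passed camera, 0 with an estimated correlation (3 at an unadjusted p below 0.05) and 80 by fry. The 4 named features kept their direction and adjusted p below 0.05 in each fit that tested them. The planned gene lists, the rdar matrix list included, were not run, for want of gene names, nor was the planned correction for length and GC content. Of 100 simulated 2-fold changes 78 were called, and how many of the others had few reads was not tested.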

Other observations

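The tests on the library-size shift and on short features, and the interval of the transfer RNA class, were chosen after their results were seen. The length correction and the tests on neighbours, runs and classes were also chosen after the data were examined, though before their own results; leaving out single libraries was planned. Features that lie close together on one strand changed together. Across 1305 adjacent pairs on the same strand within 50 bases, log2 fold changes had a Spearman correlation of 0.613, against 0.253 for 1199 same-strand pairs farther apart and 0.221 for 1204 pairs on opposite strands; these are correlations across features, which are not independent replicates. The difference between close same-strand and opposite-strand pairs was 0.392 (95% bootstrap interval 0.325 to 0.459). Opposite-strand pairs were taken at any distance, so this difference does not separate strand from closeness. Where both members were called, 89.5% of the close pairs went the same way. The share was 66.2% for same-strand pairs farther apart and 66.0% for opposite-strand pairs. Transcription in same-strand units is a hypothesis for this pattern, and closeness alone was not set apart from it. Runs with calls in both directions numbered 32 of 144, fewer than the 73 to 106 that 1000 shuffles of the calls gave. Among called members of at least 20 CPM, the widest of these runs lay at 2148854 to 2165352 (minus strand), where 9 of 20 features were higher and 3 lower, with log2 fold changes from 2.55 to -1.46. A second, at 988676 to 993443 (minus strand), held 2 higher and 1 lower among 5 features, from 2.92 to -0.73. Both were picked for their spread after the data were examined.

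Over 2535 features with a mean of at least 20 CPM the median SD of log2 (CPM + 0.5) was 0.213 in controls and 0.159 with clarithromycin, and 64.0% of features were wider in controls. Over pairs of libraries, the control median was 0.150, 0.189 or 0.190 without replicate 1, 2 or 3, and the treated median 0.0999, 0.136 or 0.162, so the ranges overlap. Controls also had lower TMM factors and, but for an overlap, fewer counted reads (2252839 to 2958125 against 2866119 to 4951945), which adds counting error. Of 11 features with a control SD of at least 1, 7 were called lower, 2 higher and 2 were not called.

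The shift of the bulk of features with library size alone, a median log2 fold change of 0.75 in edgeR and 0.764 from mean log2 CPM, was weighed against the makeup of the libraries. With library sizes taken without the 10 most abundant features the median was 0.223. The shares of reads already given fix this value at about that size (a drop of 0.539 from the group shares, 0.541 observed), so it adds no support for abundant features as the cause. Features of ribosomal RNA size differed too little in share for their depletion to be the main source: without them the median stayed at 0.720, a drop of 0.0445 that follows from their shares. Whether the shift goes with a real change in RNA content per cell stays open, since counts give no absolute scale.

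The rise of features of transfer RNA size was weighed against feature length and against 1 library. Features of 150 bases or less with a single entry had a median log2 fold change of -0.180 (95% bootstrap interval -0.521 to -0.0248), so short features as such did not share the rise. After the per-library length correction the class median was 0.315 (unadjusted camera p 0.0368, against 0.00318 before). That correction was fitted on all tested features, this class included, and may absorb part of the class's own rise. It therefore cannot tell whether part of the rise goes with length. Without clarithromycin replicate 3, the library with the highest share of such reads, the class median was 0.264 with a 95% bootstrap interval of -0.0937 to 0.625, too wide to settle whether 1 library carries the rise. An effect of clarithromycin on these RNAs stays open too, since the call was lost with an estimated correlation.

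The number of changed features was weighed against length and other splits. Single-entry features over 1200 bases had a median log2 fold change of -0.289 (205 higher, 419 lower) and those of 300 to 600 bases 0.155 (278 higher, 179 lower), relative to a median of -0.06; with library size alone these medians were 0.51 and 0.97. After a per-library length correction 2049 of the 2267 calls (90.4%) were still made in the same direction, which argues against length as their main source. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many as 2267 changed features or 1315 changed at least 2-fold in edgeR. The highest of the other splits gave 0 of each, with 12 to 87 features at an unadjusted p below 0.05 against 2489. Each other split holds libraries of both groups on each side, so the group difference widens the spread within sides and lowers these counts. The 0 is therefore no reference for the number that unchanged features would give. For runs passing camera the real split gave 22 and the highest other split also 22, so 2 of 10 splits gave as many. With 10 splits the share cannot be under 0.05.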
